A study of Danio rerio with 12 samples.

How the data were processed

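DNA replication timing was measured by sequencing genomic DNA of S-phase cells. Per the labels' protocols, zebrafish embryos were staged by eye, fixed in ethanol and stored, and for 28hpf embryos and ZTF fibroblasts the cells were stained with propidium iodide and sorted by DNA content into G1 and S fractions. The labels describe the 28hpf and ZTF samples as paired G1 and S sequencing and the earlier stages as S samples alone. What the earlier stages were divided by is not given in the sources used here. The 8 earlier-stage files share 1 grid of positions with the authors' average of the first 28hpf experiment.

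The deposited values are scores made by the authors, 1 per position, in files without a header. Higher is taken as earlier replication, from the ratio of S to G1 in the labels. The files were tested for scaling: in each, points outside chromosome 4 had a mean of 0 and an SD of 1. Amplitude is therefore lost, and a shift of the whole genome cannot be seen. The profiles are smooth along the chromosome, so neighbouring bins are not independent, and the smoothing method is not given in the sources used here. Per the submitters' processing notes, bcl2fastq, BWA and Picard were used with the GRCz10 build, and no versions are given in the sources used here. Read counts were not used here, so the depth is unknown. The number of positions per sample, 122239 to 368877, and the gaps between them set how many values stand behind a bin, with the longest gap between 211695 and 231140 bp.

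The series has 18 deposited files, 12 with 1 sample each and 6 averages by the authors over replicates. The averages were set against means of the sample files, with Pearson's r of 0.994 to 1.00, and were otherwise not used. Groups and replicate numbers were taken from the sample titles. The third 28hpf sample comes from a second experiment and is called replicate 3. The labels do not say that replicates came from separate clutches, so limma p-values measure the spread between these samples, which may be technical.

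For each sample, scores were averaged in bins of 100 kb along the 25 chromosomes. Of 13411 bins, 13234 had at least 3 points in each of the 12 samples and were tested. Scores were used as deposited. All 11 embryo samples were fitted together with a mean per stage in limma 3.58.1 (lmFit and eBayes, R 4.3.3), so that the stages share 1 estimate of the spread, with 6 residual and 12.1 prior degrees of freedom. The 5 comparisons were each step between neighbouring stages and 28hpf against pre-MBT, two-sided, with Benjamini-Hochberg adjustment over bins and a threshold of 0.05. A moderated F test covered all 5 stages. Means per chromosome were tested the same way in 26 rows, with chromosome 4 split at 28 Mb into a short and a long arm. The boundary was fixed before the data were examined, as were the design, the rule for named regions and the alternatives not listed below as chosen later.

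Neighbouring passing bins of 1 direction, with gaps of up to 1 bin, were merged into regions. The text names from the 6 regions with the largest peak change in each direction and comparison, with at most 2 per chromosome and direction. For ZTF the bins with the largest difference from the 28hpf mean were taken, at least 2 Mb apart. Regions that are named for their length, and whole chromosomes, fall outside this rule and were chosen after their values were seen. No annotation of the GRCz10 build was used here, so regions are given by coordinates, and the planned tests of gene lists, gene density and GC content were not run.

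The step size between stages is the root mean square difference of stage means over bins, with the variance expected from replicates subtracted. The trend over stages used each earlier sample's correlation with the mean 28hpf profile, by exact permutation over 40320 orderings of 8 samples (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). Figures were drawn with matplotlib. Means at chromosome ends were set against 10000 rotations of the genome-wide change profile, a circular permutation test, two-sided.

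The limma step was tested on simulated data for Bud against Shield over 13234 bins. It recovered 0 of 50 bins changed by 0.5, 23 of 50 changed by 1.0, and all 50 changed by 2.0 or by 3.0. Among 13034 unchanged bins it passed 4. Changes of 0.5 were thus missed in this simulation, in which few bins changed. Its recovery does not carry over to comparisons with many changed bins, and a change of 0.503 passed for 28hpf against pre-MBT.

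The alternatives were other scalings (median and MAD, quantile, and standardized over all bins or outside chromosome 4), bins of 50 and 200 kb, at least 1 or 5 points per bin, a trended and robust variance, only the groups compared, the replicate number as a block, stricter thresholds, the second 28hpf experiment left out, other boundaries of the long arm (24 and 35 Mb), and each replicate left out in turn. For the trend over stages and for ZTF, chromosome 4 was also left out. Chosen after seeing the data were leaving out chromosome 4 or bins within 2 Mb of a chromosome end for the counts of bins, leaving out the 2 pre-MBT or the 2 Bud samples or taking 28hpf replicate 3 alone for the trend, and all alternatives for replicate correlation (bin width, points per bin, no chromosome 4).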

Results

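Replication timing, the order in which parts of the genome are copied during S phase, was profiled along the 25 chromosomes of zebrafish (Danio rerio) in 12 samples. The embryo series had 11 samples from 5 stages. There were 2 samples from embryos before the mid-blastula transition (pre-MBT, 512 cells), 2 from dome stage, 2 from shield stage, 2 from bud stage and 3 from embryos at 28 hours post fertilization (28hpf). The remaining sample, ZTF, came from primary fibroblasts grown out of adult tail fin and had no replicate. Each deposited profile listed a score per genomic position, with higher scores where replication was earlier. The 8 samples of the 4 earlier stages shared 265255 positions with a median spacing of 4679 bp. The 28hpf profiles held 122239, 142974 and 368877 positions in replicates 1, 2 and 3, and ZTF held 191234. Read depth is unknown, so precision is judged here from the spread between samples. Scores outside chromosome 4 had a mean of 0 and a standard deviation of 1 in every file. A difference between stages is therefore relative to the rest of the profile and cannot show the length of S phase. Earlier and later below describe the score, and sources of a difference other than the order of replication are taken up at the end. Values below are means over bins of 100 kb, of which 13234 were tested, with positions on the GRCz10 build.

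The first question was how alike the profiles of 1 stage were, and how they compared across development. Replicates of a stage correlated across bins at Pearson's r of 0.848 for pre-MBT, 0.894 for Dome, 0.888 for Shield and 0.905 for Bud, and at 0.943 to 0.966 for the 3 pairs of 28hpf samples. Dome and Shield were nearly as close to each other as their own replicates were, with a mean r of 0.869 over 4 pairs (0.847 to 0.890). Pre-MBT profiles correlated with Dome at a mean r of 0.738, with Shield at 0.654, with Bud at 0.378 and with 28hpf at 0.189. The 2 Dome libraries differed, with 0.780 and 0.820 for Dome replicate 1 and 0.686 and 0.665 for Dome replicate 2. Bud and 28hpf profiles correlated at 0.779. These correlations are across bins, which are smoothed and not independent of one another.

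**Figure D1:**
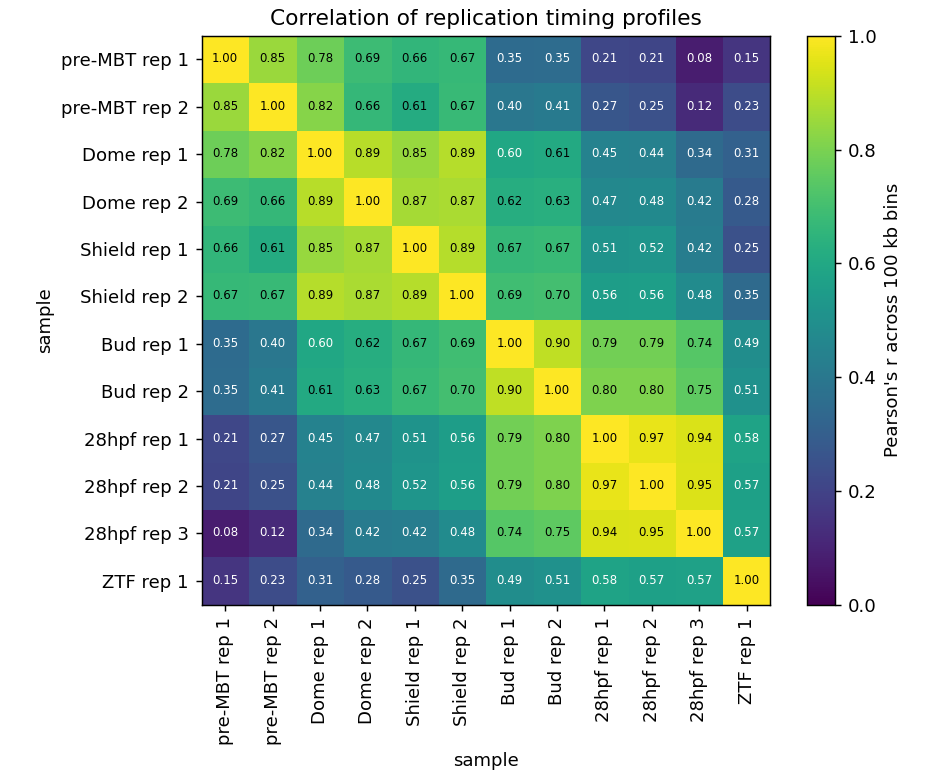
Pearson's r across 100 kb bins for each pair of the 12 samples, ordered by stage on both axes and coloured from 0 to 1. Correlation fell with distance in development, from a mean of 0.738 between pre-MBT and Dome to 0.189 between pre-MBT and 28hpf.

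Across the 5 embryo stages, 9802 of 13234 bins (74.1%) differed in timing (limma moderated F test, Benjamini-Hochberg adjusted p under 0.05). The steps between neighbouring stages were of unequal size. After removal of the part expected from replicate spread, the root mean square change was 0.513 from pre-MBT to Dome, 0.211 from Dome to Shield, 0.670 from Shield to Bud and 0.565 from Bud to 28hpf. Over the whole interval it was 1.21. Without the long arm of chromosome 4, the step from Shield to Bud was 0.536.

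**Figure D2:**
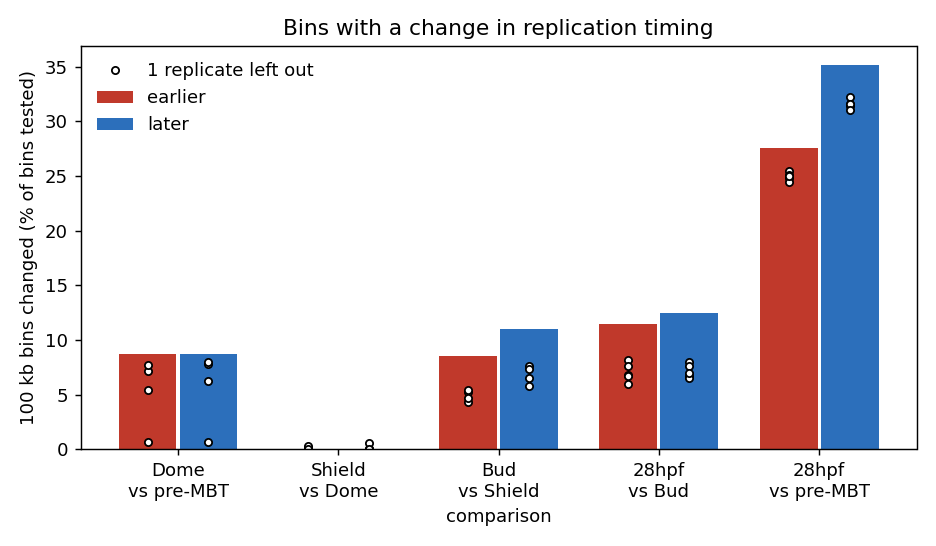
Percentage of tested 100 kb bins that became earlier (red bars) or later (blue bars) in each of the 5 comparisons, by limma with an adjusted p under 0.05. Open circles give the same percentage with 1 replicate left out. Without Dome replicate 2, the bins changed between pre-MBT and Dome fell to 1.29% in both directions together.

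The comparison of Dome with pre-MBT asked how timing changed across the mid-blastula transition, the point at which zygotic transcription begins in earnest. Ends of chromosomes moved toward earlier replication, and bins elsewhere moved in both directions. On chromosome 11, the bin from 45000001 to 45100000 rose from -3.47 ± 0.430 (SD, n = 2) to -0.823 ± 1.23 (SD, n = 2), a change of 2.65 ± 0.391 (SE, limma adjusted p = 0.00134). The start of chromosome 21, from 1 to 100000, rose by 2.53 ± 0.637 (SE, limma adjusted p = 0.0140). Of the 6 named regions with the largest gains, 5 had their peak within 1 Mb of a chromosome end. The exception was on chromosome 23, where the longest region of gain spanned 2200 kb from 43500001 to 45700000 and peaked 1.72 Mb from the end. The largest shift to later replication was on chromosome 1 at 57500001 to 57600000, where the score went from 1.14 ± 0.106 (SD, n = 2) to -1.92 ± 0.461 (SD, n = 2). None of the 6 named regions of loss peaked within 1 Mb of an end, although that on chromosome 1 lay 1.32 Mb from one. A region on chromosome 8 with its peak at 34600001 to 34700000 began at 5.24 ± 1.03 (SD, n = 2) and remained early at 2.79 ± 1.53 (SD, n = 2) in Dome, although as few as 3 positions lay behind this bin in a sample.

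In all, 2301 bins (17.4%) passed in this comparison, 1151 toward earlier and 1150 toward later replication, and they formed 404 regions of gain and 431 of loss. Without bins within 2 Mb of a chromosome end, 808 bins were earlier and 1172 later. The end bins were left out after scaling, and a profile mean of 0 offsets a rise at the ends by a fall elsewhere. Whole chromosomes shifted less. The largest change was that of the short arm of chromosome 4, which rose from 0.0899 ± 0.114 to 0.405 ± 0.0131 (SD, n = 2 each; limma adjusted p = 0.00125 over 26 chromosome rows). Chromosomes 12 and 18 became later, with changes of -0.182 ± 0.0317 and -0.176 ± 0.0249 (SE) and adjusted p of 0.00193 and 0.00125. The count rests largely on 1 library. Without Dome replicate 2 it was 171 bins (1.29%), and with only the 4 samples compared in the fit it was 6.28% of bins.

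Between Dome and Shield, the interval that leads into gastrulation, no bin passed the limma test, with 1483 bins at an unadjusted p under 0.05. That is more than a share of 0.05 of the 13234 bins, which would be reached on average if no bin changed. The root mean square change beyond replicate spread was 0.211, so an absence of change is not shown. With a trended, robust variance, limma also passed 0 bins, with 1474 unadjusted. None of the 26 chromosome rows passed. On chromosome 11, the end bin at 45000001 to 45100000 was -0.823 ± 1.23 in Dome and -0.222 ± 0.0141 in Shield (SD, n = 2 each), and the site on chromosome 8 at 34600001 to 34700000 was 2.79 ± 1.53 and 2.13 ± 0.881 (SD, n = 2 each). Without Shield replicate 1, 117 bins (0.884%) passed, and 1 bin passed without Dome replicate 1 or without Shield replicate 2.

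The comparison of Bud with Shield covers most of gastrulation, up to its end. The long arm of chromosome 4, the gene-poor, repeat-rich heterochromatic arm of this genome, taken as a whole, moved from earlier than average to the latest part of the profile. Its mean over 383 bins beyond 28 Mb was 0.524 ± 0.452 in pre-MBT, 0.522 ± 0.198 in Dome and 0.401 ± 0.461 in Shield, and then -1.82 ± 0.0372 in Bud (SD, n = 2 each). The change from Shield to Bud was -2.22 ± 0.233 (SE, limma adjusted p = 0.000133), and the next step, to -1.83 ± 0.119 (SD, n = 3) at 28hpf, was -0.00792 ± 0.212 (SE, adjusted p = 0.971). Of the arm's bins, 311 (81.2%) passed toward later replication and 1 toward earlier. The arm was not uniform, since the window from 70000001 to 75000000 was already at -0.276 ± 0.406 in Shield and went to -0.857 ± 0.0177 in Bud (SD, n = 2 each), while the window from 45000001 to 50000000 went from 0.286 ± 0.952 to -2.20 ± 0.0134. The last window, from 75000001 to 80000000, was already late in pre-MBT, at -2.04 ± 0.173, and in Shield, at -0.779 ± 0.252. It was at -1.46 ± 0.178 in Bud (SD, n = 2 each) and -1.28 ± 0.0739 (SD, n = 3) at 28hpf. The short arm went the other way, from 0.339 ± 0.0501 to 0.478 ± 0.0363 (SD, n = 2 each; limma adjusted p = 0.0392).

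**Figure D3:**
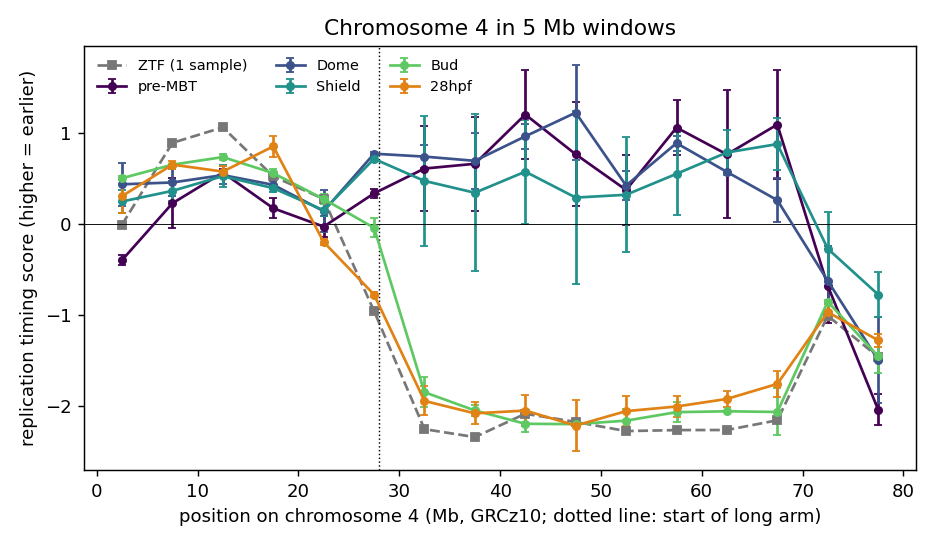
Mean replication timing score (vertical axis, higher is earlier) in 5 Mb windows along chromosome 4 (horizontal axis, Mb), with points and bars for the mean and SD of each embryo stage (n = 2, and n = 3 at 28hpf) and squares for the single ZTF sample. Right of the dotted line at 28 Mb, the Bud, 28hpf and ZTF profiles lie near -2 as far as 70 Mb, below all 3 earlier stages.

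Elsewhere the losses were sharpest at a few interior sites. On chromosome 16, the bin from 36300001 to 36400000 went from 1.92 ± 1.41 to -2.33 ± 0.145 (SD, n = 2 each), and on chromosome 8, the bin from 34700001 to 34800000 went from 1.88 ± 0.872 to -1.76 ± 0.265 (SD, n = 2 each). A region of chromosome 5 from 41500001 to 42900000 also became later, with a change of -2.93 ± 0.380 (SE) at its peak. The sparsest sample held 4, 5 and 8 positions in these peak bins on chromosomes 16, 8 and 5. The median over all bins was 9, and mapping at these sites was not tested. Shifts toward earlier replication were smaller, between 1.99 and 2.26 at the 6 named peaks. The strongest was also on chromosome 5, where the bin from 48900001 to 49000000, the peak of a region of 1600 kb, rose from -0.646 ± 0.0458 to 1.61 ± 0.343 (SD, n = 2 each; limma adjusted p = 7.97e-06). On chromosome 21, the bin from 23200001 to 23300000 rose from -1.33 ± 0.332 to 0.883 ± 0.429 and was at 1.86 ± 0.141 (SD, n = 3) at 28hpf. On chromosome 13, the mean over the whole chromosome rose by 0.200 ± 0.0302 (SE, adjusted p = 0.00124), and chromosome 3 fell by 0.205 ± 0.0330 (SE, adjusted p = 0.00136).

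In total 2587 bins (19.5%) passed, 1130 toward earlier and 1457 toward later replication. With the deposited scores, 1129 earlier and 1146 later bins lay among the 12851 outside the chromosome 4 long arm. The direction held by most bins depends on the scaling, since 1358 were earlier and 1180 later when profiles were standardized over all bins, and 1271 and 1137 with quantile normalization. The count was 1343 without Shield replicate 1, 1691 without Shield replicate 2, 1479 without Bud replicate 1 and 1689 without Bud replicate 2. The largest drop, at chromosome 4 from 61400001 to 61500000, rests largely on 1 library, since the bin was at 0.586 in Shield replicate 1 and 6.30 in Shield replicate 2.

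From Bud to 28hpf, the interval in which the body plan gives rise to organs, interior regions of many chromosomes moved in both directions. On chromosome 5, the bin from 17100001 to 17200000 stayed late through Bud, at -0.880 ± 0.00914 (SD, n = 2), and rose to 1.72 ± 0.207 (SD, n = 3), a change of 2.60 ± 0.223 (SE, limma adjusted p = 8.15e-06). On chromosome 19, the bin from 22200001 to 22300000 rose from -1.39 ± 0.306 (SD, n = 2) to 1.201 ± 0.312 (SD, n = 3). Chromosome 6 held 2 of the 6 named gains, peaking at 14300001 and 6400001. The largest shift to later replication, on chromosome 12 at 6400001 to 6500000, followed a peak at Bud. That bin was at 0.0593 ± 0.0206 in Shield, 1.18 ± 0.338 in Bud (SD, n = 2 each) and -1.72 ± 0.236 (SD, n = 3) at 28hpf. On chromosome 14, the bin from 34100001 to 34200000 likewise went from 0.732 ± 0.216 in Shield to 1.76 ± 0.554 in Bud (SD, n = 2 each) and -0.897 ± 0.0705 (SD, n = 3) at 28hpf. The longest region of gain was at the start of chromosome 25, 2800 kb from 300001 to 3100000, and the longest region of loss was on chromosome 22, 2300 kb from 6700001 to 9000000.

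Of all bins, 3168 (23.9%) passed, 1520 toward earlier and 1648 toward later replication. Chromosome 18 became earlier by 0.137 ± 0.0227 (SE, limma adjusted p = 0.00505), and 7 of 26 chromosome rows passed. The 28hpf samples came from 2 experiments, with replicates 1 and 2 from the first and replicate 3 from the second, and the earlier stages belong to the first. Within the first experiment 1782 bins (13.5%) passed, 895 earlier and 887 later, while the second holds no Bud sample. The labels give 28hpf as paired G1 and S sequencing and Bud as S samples alone. Stage and the making of the score thus cannot be told apart, also within the first experiment. The count was 2016 without 28hpf replicate 2, 1645 without Bud replicate 1 and 1814 without Bud replicate 2.

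Over the whole interval from pre-MBT to 28hpf, the ends of chromosomes became earlier and a set of interior sites, early in pre-MBT, became late. All 6 named regions of gain peaked within 1 Mb of an end. The last bin tested on chromosome 3, from 62300001 to 62400000, rose from -3.65 ± 0.131 (SD, n = 2) to 1.04 ± 0.647 (SD, n = 3), a change of 4.69 ± 0.361 (SE, limma adjusted p = 2.86e-08). The first bin of chromosome 25 rose by 4.63 ± 0.386 (SE), within a region of 3100 kb. On chromosome 18, the bin from 50900001 to 51000000 passed through -4.12 ± 0.392, -2.11 ± 1.42, -1.41 ± 0.917 and 0.0605 ± 0.0386 in pre-MBT, Dome, Shield and Bud (SD, n = 2 each), and reached 0.473 ± 0.684 (SD, n = 3) at 28hpf. Of the named losses, the site on chromosome 8 at 34600001 to 34700000 went from 5.24 ± 1.03 (SD, n = 2) to -1.53 ± 0.329 (SD, n = 3), a change of -6.77 ± 0.507 (SE, limma adjusted p = 2.31e-08). On chromosome 22, a region of 4600 kb from 5600001 to 10200000 went from 3.16 ± 0.390 (SD, n = 2) to -1.60 ± 0.0928 (SD, n = 3) at its peak. On chromosome 5, the bin from 41900001 to 42000000 went from 3.39 ± 0.445 (SD, n = 2) to -1.40 ± 0.389 (SD, n = 3), and the longest region of loss was 7800 kb on chromosome 4, from 37000001 to 44800000. The sparsest sample held 3, 5 and 8 positions in the peak bins of loss on chromosomes 8, 22 and 5. It held 10, 11 and 17 in the end bins on chromosomes 3, 25 and 18, and the median over all bins was 9.

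By distance from the chromosome end, a grouping chosen after the regions were seen, bins within 0.5 Mb had a mean of -1.97 ± 0.328 in pre-MBT, -0.834 ± 0.760 in Dome, -0.500 ± 0.417 in Shield, 0.124 ± 0.0965 in Bud (SD, n = 2 each) and 0.266 ± 0.267 (SD, n = 3) at 28hpf. Bins 20 to 40 Mb from an end went from 0.625 ± 0.00285 (SD, n = 2) in pre-MBT to 0.130 ± 0.0749 (SD, n = 3) at 28hpf. Part of this fall can follow from the scaling, since a profile mean of 0 offsets a rise at the ends by a fall elsewhere.

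**Figure D4:**
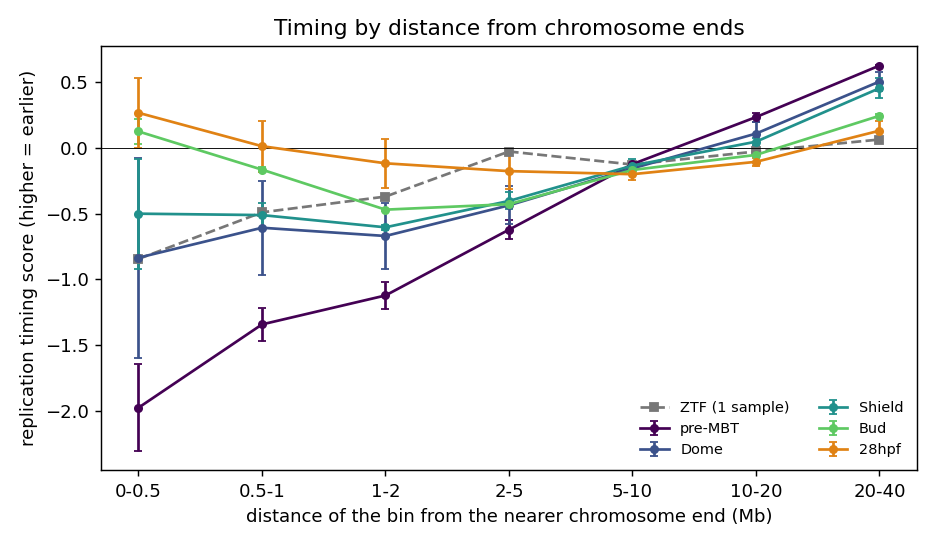
Mean replication timing score (vertical axis, higher is earlier) of bins grouped by distance from the nearer chromosome end (horizontal axis, Mb), with points and bars for the mean and SD of each embryo stage (n = 2, and n = 3 at 28hpf) and squares for the single ZTF sample. Within 0.5 Mb of an end the mean rises from -1.97 in pre-MBT to 0.266 at 28hpf, and at 5 to 10 Mb the stages lie together.

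Between pre-MBT and 28hpf, 8301 bins (62.7%) passed, 3648 toward earlier and 4653 toward later replication. Under other scalings the 2 directions lay closer, at 4030 and 4121 when standardized over all bins, 3958 and 4093 with quantile normalization, and 3934 and 4087 with median and MAD. Without bins within 2 Mb of a chromosome end they lay further apart, at 2920 and 4652. These bins were left out after scaling, so an excess of later bins can follow from the rise at the ends. Among the passing bins, 59.6% of those that became earlier and 57.3% of those that became later crossed the profile mean. Of the 26 chromosome rows, 18 passed, 6 toward earlier and 12 toward later. The long arm of chromosome 4 changed by -2.35 ± 0.212 (SE, limma adjusted p = 1.28e-05), chromosome 1 by -0.314 ± 0.0213 (adjusted p = 3.33e-06), chromosome 8 by -0.268 ± 0.0241 (adjusted p = 1.28e-05) and chromosome 23 by 0.242 ± 0.0250 (adjusted p = 2.40e-05). Within the first experiment, 7438 bins (56.2%) passed, and there too pre-MBT is labelled as S samples alone and 28hpf as paired G1 and S.

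Likeness to the 28hpf profile rose stage by stage. Each earlier sample was correlated across bins with the mean of the 3 samples at 28hpf, giving r of 0.193 ± 0.0322 for pre-MBT, 0.439 ± 0.0317 for Dome, 0.518 ± 0.0349 for Shield and 0.792 ± 0.0112 for Bud (SD, n = 2 each). Over the 8 samples this r rose with stage order, with Spearman's rho of 0.976 and Pearson's r of 0.977, each with p = 0.000794 in a two-sided exact permutation test. Each p of this test, also below, treats samples as independent, although they are replicates of a few stages and may be technical. The p is thus lower than an ordering of the stages alone could give. A rho of 0.976 is the largest that 4 pairs of tied samples allow, so it shows the order of the stages and not the size of the rise. Without the 2 pre-MBT samples, Pearson's r was 0.945, and without the 2 Bud samples it was 0.946 (p = 0.0222 each, exact permutation test). With 28hpf replicates 1 and 2 alone as the later profile, the samples' r went from 0.213 and 0.260 in pre-MBT to 0.796 and 0.812 in Bud, and with replicate 3 alone from 0.0793 and 0.120 to 0.737 and 0.751.

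**Figure D5:**
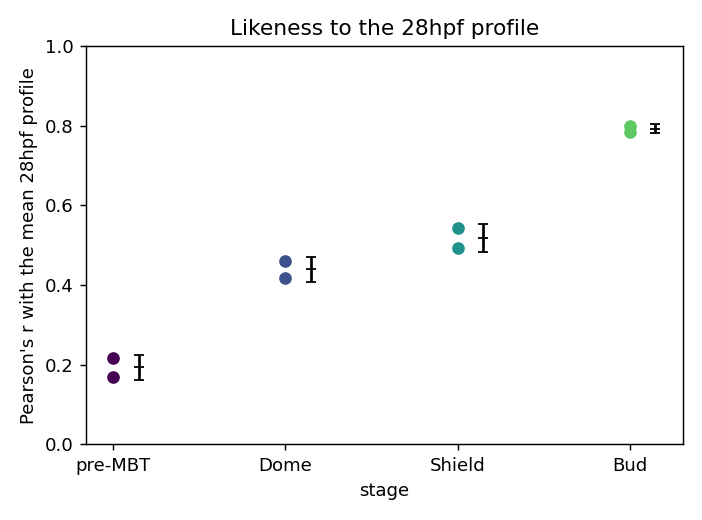
Pearson's r across 100 kb bins with the mean 28hpf profile (vertical axis) for each sample of the 4 earlier stages (horizontal axis, coloured points), with black bars for the mean and SD (n = 2 each). The means rise from 0.193 in pre-MBT to 0.792 in Bud.

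The ZTF fibroblasts, a differentiated adult cell type, were compared with the 28hpf embryos as 1 sample without a test. Their profile correlated with 28hpf at a mean r of 0.575 (0.568 to 0.582), with Bud at 0.499 and with pre-MBT at 0.193. The chromosome 4 long arm was late in both, at -2.01 in ZTF and -1.83 ± 0.119 (SD, n = 3) at 28hpf. ZTF lay outside the range of the 28hpf samples by at least 1 in 2756 bins (20.8%), 1450 earlier and 1306 later. The largest differences toward earlier replication were on chromosome 7 at 43700001 to 43800000, with 2.95 in ZTF against -0.586 ± 0.182 (SD, n = 3), and on chromosome 2 at 46100001 to 46200000, with 2.43 against -1.10 ± 0.120 (SD, n = 3). Of the 6 largest toward later replication, the bin on chromosome 13 at 51700001 to 51800000 was at -2.58 in ZTF and 0.749 ± 0.335 (SD, n = 3) at 28hpf, and lies at the chromosome end. Chromosome 12 as a whole was at 0.105 in ZTF and -0.242 ± 0.0260 (SD, n = 3) at 28hpf, and chromosome 22 at -0.204 and 0.0745 ± 0.0325.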

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

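The counts for 28hpf against pre-MBT and across all 5 stages stayed within 1.5 times of their reported values under every alternative run, at 50.1% to 64.0% and 57.6% to 75.2% of bins. The fall of the chromosome 4 long arm from Shield to Bud kept its direction and its call under all 15 alternatives (-2.54 to -1.52), as did that from pre-MBT to 28hpf under all 17 (-2.67 to -1.62). Among the 17, leaving out the second experiment and leaving out 28hpf replicate 3 are the same fit. The trend in likeness to 28hpf kept its call under all 21, although linear rescaling (median and MAD, or over all bins) could hardly alter a correlation. Its rho was at the largest value the ties allow in each and cannot show a change in size, while Pearson's r with stage order ran from 0.945 to 0.989. The share of ZTF bins outside the 28hpf range ran from 14.6% to 21.3%, and mean replicate correlation from 0.913 to 0.916. At an adjusted p under 0.01, the bins changed fell to 4.51% (Dome vs pre-MBT), 8.70% (Bud vs Shield) and 10.5% (28hpf vs Bud), as a stricter threshold must lower them. With only the 2 groups in the fit, Dome vs pre-MBT gave 6.28% (831 bins against 2301), Bud vs Shield 14.7% and 28hpf vs Bud 32.2% (4263 bins). Replicate spread was unequal. The root mean square difference expected from it was 0.356, 0.327 and 0.261 in these 3 comparisons, the last with 3 samples at 28hpf. A shared spread can thus be too small for the first and too large for the last. Counts of passing bins are therefore not directly comparable between steps. How much of the shift this explains, beside the smaller number of samples per fit, was not tested. With median and MAD scaling, earlier and later bins were 1455 and 1142 for Dome vs pre-MBT and 1418 and 1274 for 28hpf vs Bud. Without the second experiment, 28hpf vs Bud gave 13.5% (1782 bins against 3168), with fewer samples. With 1 replicate left out, the ranges were 1.29% to 15.7% for Dome vs pre-MBT, 0% to 0.884% for Shield vs Dome, 10.1% to 12.8% for Bud vs Shield and 12.4% to 16.1% for 28hpf vs Bud. A lone sample is then assumed to vary like the other groups. The drop to 171 bins without Dome replicate 2 exceeds that from leaving out Dome replicate 1 (2076 bins), and the cause was not tested.

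The arm values that do not pass the test, all within 1 standard error of 0 in the reported fit, changed sign under some alternatives and passed under none; the cause was not tested. Dome vs pre-MBT (-0.00167 as reported) was 0.00547 with median and MAD scaling, 0.0179 with quantile normalization, 0.0126 and 0.0169 when standardized over all bins or outside chromosome 4, 0.0556 in 50 kb bins, 0.0254 with at least 5 points per bin, 0.0310 from 24 Mb, and -0.321 to 0.318 with 1 replicate left out. Shield vs Dome (-0.122) was 0.0526 in 50 kb bins, 0.0632 with at least 5 points, and -0.448 to 0.204 with 1 replicate left out. 28hpf vs Bud (-0.00792) was 0.167 with median and MAD scaling, 0.0008 standardized outside chromosome 4, 0.0295 in 200 kb bins, 0.0400 with at least 1 point, 0.0676 from 35 Mb, and -0.0663 to 0.0523 with 1 replicate left out.

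Replicate numbers do not pair the samples: deviations of same-numbered samples from their stage means correlated across bins at -0.228 to 0.176 over pairs of stages. With the replicate block, over replicates 1 and 2 only, 28hpf vs Bud gave 12.5% of bins (1659), Dome vs pre-MBT 13.9% and Bud vs Shield 16.5%. Alternatives that need a genome or annotation of the build (GC correction, gene density, gene lists) were not run. Bins on the chromosome 4 long arm hold a median of 4 points in their sparsest sample, against 9 over all bins, which limits values of single bins there.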

Other observations

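Apart from some values for the chromosome 4 long arm, the tests in this part were chosen after the profiles were seen. The arm's changes under other scalings, bin widths and point numbers, or with a library left out, used settings fixed before the data were examined. The comparison of the chromosome 4 long arm with bins of like point number had its outcomes written down before it was run, and all other outcomes were written afterwards. The explanations are hypotheses tested on the data that raised them.

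Chromosome ends became earlier over development, though unevenly by step. Each p for the ends comes from a circular permutation test, 10000 rotations of the change profile. It measures where the bins lie along the genome and not the spread between samples, which the values with a library left out show. Over 502 bins within 1 Mb of an end, the mean rose by 0.938 from pre-MBT to Dome, with 50 of 50 ends higher (permutation p = 0.0003, 0.0005 adjusted over 5 comparisons). It rose by 0.486 from Shield to Bud, with 43 of 50 ends higher (permutation p = 0.0001, the smallest the rotations can give, 0.00025 adjusted), and by 0.304 without Shield replicate 2. The step from Dome to Shield depends on single libraries, at 0.216 with all samples (permutation p = 0.0006, 0.00075 adjusted), -0.179 without Dome replicate 1 and 0.0341 without Shield replicate 1. The step from Bud to 28hpf, 0.160 (permutation p = 0.0342, also 0.0342 adjusted), fell to 0.0314 without 28hpf replicate 3. In the step from pre-MBT to Dome the rise was 0.543 without Dome replicate 2 and 1.33 without Dome replicate 1. In the single ZTF sample the same bins lay below 28hpf by a mean difference of -0.809, and were lower at 46 of 50 ends, without a test.

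For the rise of 1.80 at the ends from pre-MBT to 28hpf, an edge effect of the smoothing may be proposed. Bins 1 to 2 Mb from an end also rose, by 1.00 (permutation p = 0.0033), so the rise was not limited to the outermost 1 Mb. The reach of the smoothing is unknown, so this does not decide on an edge effect, which stays open. End bins held a median of 11 points in their sparsest sample, against 9 over all bins, which argues against sparse mapping. Rotations of the profile reached the observed mean in none of the draws (permutation p = 0.0001, the smallest they can give). A denominator shared within the first experiment stays open: the closest pair of Bud and pre-MBT samples differed by 1.44 at the ends, against at most 0.791 between replicates of any stage, but scaling can change the weight of a shared part, and 28hpf replicates 1 and 2 (-0.0459 and 0.0697) lay below replicate 3 (0.397). GC content was not tested and also stays open, so a change in the order of replication with stage is 1 hypothesis among those left.

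The fall of the chromosome 4 long arm from Shield to Bud might reflect its sparse positions, since bins elsewhere with as few points also fell, by 0.605 on average (a change of -0.605). That is well short of the change on the arm, -2.22, so sparse positions do not account for the whole fall and may account for part of it. Under the 4 other scalings the smallest change was -1.99 ± 0.226 (SE). With 1 Shield or Bud library left out it was -1.89 ± 0.220 (SE). The change was -2.30 ± 0.222 (SE) with at least 1 point per bin and -1.67 ± 0.196 (SE) with at least 5. In 50 kb bins it was -1.52 ± 0.205 (SE). The fall was thus smaller, though still present, when sparser bins were left out. Copy number of the arm's repeats and their mapping were not tested and stay open beside a change in timing between the stages.

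All 8 earlier samples matched the first 28hpf experiment more closely than the second, and each correlated across bins with the difference of the first minus the second. That r was 0.439 and 0.461 in pre-MBT, 0.336 and 0.197 in Dome, 0.330 and 0.271 in Shield, 0.198 and 0.203 in Bud, and 0.0223 in ZTF, a different cell type. A denominator or batch shared by the first experiment would raise all 4 stages, yet the lowest pre-MBT value exceeded the highest Bud value by 0.236, against at most 0.139 between replicates; since scaling removes amplitude, this leaves the hypothesis open. Embryos of the second experiment that were further in development could give such a gradient too, which was not tested. Both hypotheses stay open, and counts that set 28hpf against earlier stages are best read with the values within the first experiment beside them.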
